A study of Mus musculus with 6 samples.

How the data were processed

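RNA was measured on 6 arrays of C2C12 cells, a mouse myoblast line that fuses into contractile myotubes when serum is lowered. Per the labels, the cells grew in 10% fetal bovine serum, were differentiated in 2% horse serum and were used as myotubes between days 4 and 7 of differentiation. The 3 insulin cultures had received 100 nM insulin for 48 h, and the 3 control cultures had been left untreated. Fresh medium every 24 h is given for the samples of both groups. The labels call the 3 arrays of each group biological replicates. For each array, 25 ng of total RNA was amplified before labelling with biotin, per the labels' protocols, so every level here is one of amplified RNA.

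The authors deposited 1 log2 value per probe set and array, made with RMA (background correction, quantile normalization and a robust summary of probes) per the submitters' processing notes, which state no version. The log base is not stated in the sources used here. Base 2 was inferred from the range of 3.15 to 14.6, which is what RMA gives on that scale, and all changes below rest on it. The table held 241576 probe sets, and array medians lay between 8.79 and 8.82. Scanner images, probe intensities and detection calls were not used here, so no probe set could be called above or below background, and the number of arrays limits the precision. Scan dates and hybridization batches are not given in the sources used here, and a batch that followed the groups would not be seen.

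Probe sets were named from GEO's platform annotation, whose symbols are old. It gave exactly 1 gene symbol for 212097 probe sets, several for 4475 and none for 25004. A gene's value on an array was the median of the log2 values of its probe sets with exactly 1 symbol, which gave 20416 genes with a median of 8 probe sets each. For 2292 genes there was 1 probe set only. Genes are printed under the annotation's symbol, with the present symbol in brackets where it differs. Present symbols came from RefSeq names and synonyms of assembly GRCm38.p6: 17621 symbols were present ones, 2668 were updated and 127 had no unambiguous match and were kept. No coordinates were used here, as no build is named for the array.

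Genes whose mean over the 6 arrays lay under the 30th percentile (7.05 on the log2 scale) were left out, which left 14291. Insulin minus control was fitted with limma 3.58.1 (lmFit and eBayes, two-sided, in R 4.3.3) without covariates, and p-values were adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05. Probe sets were fitted in the same way, with the same percentile filter. A standard error (SE) is that of the moderated limma fit, and SDs are over the 3 arrays of a group. A change of 1 on the log2 scale is a doubling. As RMA equalizes the arrays, every change is relative to the other transcripts on the array, and a change in total RNA per cell would not show.

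Before the data were examined, 35 gene lists were fixed. They cover insulin signalling and its transcriptional targets, metabolism, mitochondria, stress responses, growth, muscle differentiation, candidate genes at type 2 diabetes loci and markers of cell types other than myotubes. The lists were compiled from general knowledge and none was chosen by the study on these samples. Each list with 5 or more tested members was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over 33 lists. Camera asks whether a list's genes moved further than other genes. Camera was repeated with a correlation estimated from the arrays, and fry, which asks whether a list's genes moved on balance one way without comparing them with other genes, was run beside it. Counts of members that rose or fell use the adjustment over all tested genes, and counts "adjusted over the list alone" use only the list's members.

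The genes named in the text were set by a rule, also fixed before the data were examined. It takes the 12 largest rises and 12 largest falls by log2 change among genes past the threshold whose insulin and control arrays did not overlap. It adds the 3 members with the smallest unadjusted p of each list called by camera, and of 6 lists whether called or not (insulin signalling, FoxO targets, lipogenesis, glycolysis, oxidative phosphorylation, mitochondrial fusion and fission). It always takes Insr, Irs1, Irs2, Slc2a1, Slc2a4, Hk2, Pdk4, Fbxo32, Srebf1, Ppargc1a and Mfn2. Other members named as examples of a group were chosen after their values were seen.

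The alternatives set in advance were the replicate number as a block, repeated quantile normalization, centring each array on its median, no filter, a filter at the 50th percentile, an intensity trend with a robust prior, array quality weights, the brightest probe set or the mean of a gene's probe sets, a gene's brighter probe sets alone, camera with an estimated correlation or on ranks, and leaving out each array in turn. A minimum change of 1.5-fold and list matching by the annotation's symbols alone were added after seeing the data.

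The fit was tested on simulated data for this comparison, with 14291 genes of which 200 were changed by known amounts. A further small set of genes was shifted together to test camera. At a true change of 0.25, 0.5, 1 and 2 on the log2 scale the fit called 2%, 60%, 92% and 100% of the 200 changed genes. Of its 142 calls 9 (6.34%) were false, and calls in the further set were not counted as false. A smaller share of genes was changed there than was called in the data (15.9%), and the simulated noise was independent between genes. The adjusted threshold depends on that share, so these rates need not hold for the data. Pairs of arrays correlated at Pearson's r of 0.977 to 0.990 over all probe sets (15 pairs), and no pair shared more than 0.1% of its values, so all 6 arrays were counted separately. Control pairs lay at 0.984 to 0.985, insulin pairs at 0.988 to 0.990 and pairs across the groups at 0.977 to 0.986. Control 2 correlated best with insulin 2 (0.9864) and control 3 with insulin 1 (0.9864). Both were thus closer to an insulin array than to any other control.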

Results

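Transcripts were measured on 6 arrays of C2C12 myotubes, with 3 untreated cultures and 3 cultures kept in 100 nM insulin for 48 h. Per the labels, the long exposure served to bring the cells into an insulin-resistant state. The series as a whole looked for type 2 diabetes candidate genes at the interface of insulin signalling and mitochondria. The comparison asked which transcripts differed between chronically insulin-treated and untreated myotubes. The first principal component of the 14291 tested genes held 58.6% of the variance and separated the groups, with scores from -21.1 to -10.2 for controls and from 13.6 to 15.8 for insulin. The next component held 18.0% and spread the controls, with control 1 at 13.3 and control 3 at -15.0.

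Of the 12 largest rises, 5 were of genes on the ATF4 and amino acid synthesis list. Slc7a11, the cystine transporter subunit xCT, went from 6.69 ± 0.37 to 10.22 ± 0.08 on the log2 scale (mean ± SD, n = 3 each), an 11.6-fold rise. Cth, which makes cysteine from cystathionine, rose 8.99-fold and Bcat1, the cytosolic branched-chain aminotransferase, 3.66-fold. Ddit3, encoding the stress transcription factor CHOP, rose 3.56-fold and Trib3, encoding a pseudokinase that binds AKT, 3.50-fold. The largest rise was in Car6, a secreted carbonic anhydrase, from 6.03 ± 0.09 to 10.36 ± 0.03 (SD, n = 3), or 20.1-fold. The control means of Slc7a11 and Car6 lay under 7.05, the level of the filter on dim genes, and signal over background was not judged, so both folds are ratios of RMA values and not exact changes of RNA. The rise of Slc7a11 on the log2 scale was 3.54, and 2.34 with its brightest probe set.

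Of the 14291 genes, 2274 (15.9%) passed limma's test at a Benjamini-Hochberg adjusted p of 0.05, with 1366 higher and 908 lower after insulin. Most changes were small: the median absolute change of the called genes was 0.41 on the log2 scale, with a mean SE of 0.084. At least 1.5-fold changes, a limit added after seeing the data, were found in 326 of the genes that rose and 95 of those that fell, and at least 2-fold changes in 45 and 15. In all 2274 called genes the 3 insulin arrays lay wholly above or below the 3 controls, as they did in 35.7% of all tested genes, where chance gives 10%. The count depended on the arrays, falling to 1234 without control 2, 1268 without insulin 1, 1045 without insulin 2 and 1111 without insulin 3. It rose to 5007 with array quality weights, where 2608 rose and 2399 fell, and to 3436 with the mean of a gene's probe sets.

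The other leading rises were of mixed kinds. Avil (advillin, an actin-binding protein) rose by 2.63 ± 0.10 on the log2 scale (SE), with 20 of its 21 probe sets going up, while its brightest probe set gave -0.17. Nefm, the medium neurofilament subunit, rose from 8.82 ± 0.03 to 11.11 ± 0.06 (SD, n = 3). Gsta3, a glutathione S-transferase, rose by 1.81 ± 0.09 (SE), the phosphatase gene Ppef1 by 1.74 ± 0.27 and the keratin gene Krt13 by 1.74 ± 0.07. Gm6596 (Usp17le) rose by 1.86 ± 0.09 on the evidence of 1 probe set, and belongs to a family of near-identical genes that was not told apart here. Limma's adjusted p for the 12 leading rises ran from 6.33e-08 for Car6 to 0.00509 for Ppef1.

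The largest fall was in Mfap5, a microfibril protein, which fell by 1.60 ± 0.09 on the log2 scale (SE). Fbln7 (fibulin 7) fell by 1.31 ± 0.08 and Postn (periostin) fell by 1.24 ± 0.17, while Aspn (asporin) changed by -1.25 ± 0.18. Cxcr4, the CXCL12 receptor, went from 11.67 ± 0.04 to 10.41 ± 0.03 (SD, n = 3). Sepp1 (Selenop), the selenium carrier, changed by -1.14 ± 0.07 (SE) and Cp (ceruloplasmin, a copper-carrying ferroxidase) by -1.09 ± 0.06. Id3, an inhibitor of myogenic helix-loop-helix factors, changed by -1.14 ± 0.07 and Myl2, the slow-muscle regulatory myosin light chain, by -1.12 ± 0.10. Gprin3, the sodium channel gene Scn7a and the GDNF receptor gene Gfra1 changed by -1.08 ± 0.11, -1.06 ± 0.16 and -1.02 ± 0.07. With the brightest probe set alone, Mfap5 (-0.54, limma adjusted p = 0.0721) and Gprin3 (-0.27, adjusted p = 0.251) no longer passed. Limma's adjusted p for these 12 genes ran from 4.08e-05 for Cxcr4 to 0.00507 for Scn7a.

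**Figure D1:**
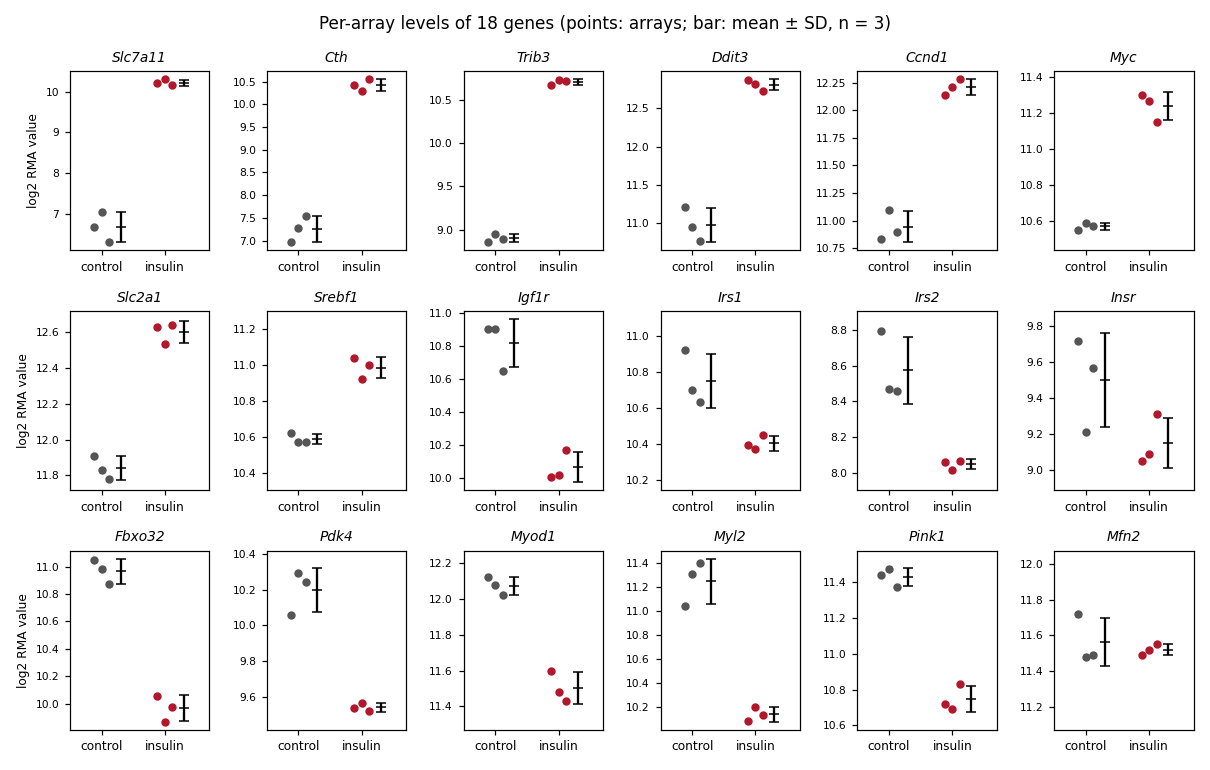
Log2 RMA values of 18 genes on each of the 6 arrays, with grey points for the 3 controls and red points for the 3 insulin arrays. Bars give mean ± SD (n = 3), each panel has its own axis range, and the groups overlap only for Insr and Mfn2.

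The ATF4 and amino acid synthesis list was called higher by camera (median change 0.34, adjusted p = 1.13e-19, and 0.0189 with an estimated correlation). Of its 43 tested members 28 rose, 1 fell and 14 did not pass, and 37 rose and 2 fell adjusted over the list alone. Aldh1l2, a mitochondrial folate enzyme, rose from 9.85 ± 0.06 to 11.37 ± 0.03 (SD, n = 3). Mthfd1l rose by 1.11, the serine synthesis gene Psph by 1.11, Shmt2 by 0.84 and Asns, asparagine synthetase, by 0.45. Atf4 itself rose by 0.35 (limma adjusted p = 0.0195). Fgf21, a secreted hormone often induced with this group, was the member that fell, by 0.39.

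Endoplasmic reticulum chaperones were not called as a group by camera. Of 26 tested members of the chaperone and unfolded protein response list, Edem1 (0.66) and Sec61b (0.25) rose and 24 did not pass, with 1 rise adjusted over the list alone. The list's median was 0.052 and camera did not call it (adjusted p = 0.471), while fry passed it as moving up on balance (adjusted p = 0.0373). The mean of the ATF4 list minus that of the chaperone list went from -0.63 ± 0.04 to -0.03 ± 0.02 (SD, n = 3), a difference of 0.60. The exact permutation test of this difference gave a two-sided p of 0.1, the smallest that 3 against 3 arrays allow.

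Antioxidant genes rose in part. In the NRF2 and oxidative stress list 11 of 28 members rose and none fell by limma (12 and 0 adjusted over the list alone), with a median of 0.13 and camera adjusted p = 3.91e-06. The call missed the threshold narrowly with an estimated correlation (adjusted p = 0.0501 with an estimated correlation). Besides Slc7a11, which the ATF4 list also holds, Nqo1 (quinone reductase) rose by 0.95 ± 0.09 (SE) and Tkt (transketolase) by 0.77 ± 0.07. The glutathione synthesis genes Gclm and Gclc rose by 0.61 and 0.47.

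Cell cycle genes rose in most cases. Of 49 tested cell cycle genes 42 rose, none fell and 7 did not pass, and 44 rose adjusted over the list alone. The median change was 0.55, and camera called the list higher (adjusted p = 9.13e-25, and 0.0491 with an estimated correlation). Ccnd1 (cyclin D1) rose by 1.27 ± 0.09 on the log2 scale (SE), the transcription factor gene Foxm1 by 0.74 ± 0.07 and the mitotic kinase gene Plk1 by 0.66 ± 0.07. Mki67, the gene of the Ki-67 antigen, rose by 0.92 and the replication helicase gene Mcm3 by 0.76. Plk1 did not pass with its brightest probe set alone (0.40, limma adjusted p = 0.0781).

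Many genes of ribosome biogenesis also rose. In the list of ribosome biogenesis and Myc targets 21 of 35 members rose and none fell (27 and 0 adjusted over the list alone), with a median of 0.35 and camera adjusted p = 9.61e-13, or 0.0491 with an estimated correlation. The median was 0.23 with the brightest probe set of each gene, where camera still called the list. Dkc1 (dyskerin) rose by 0.90 ± 0.07 (SE), Srm (spermidine synthase) by 0.85 ± 0.06 and Myc by 0.67 ± 0.07, which its brightest probe set put at 0.50 without passing (limma adjusted p = 0.0581). Cytosolic ribosomal proteins had a median of 0.034 and were not called by camera (adjusted p = 0.187). Among 61 of them Rpl23a and Rpl35a rose, by 0.69 and 0.51, which holds adjusted over the list alone. On control 1 this list's mean lay at -0.12 from its mean over the 6 arrays, and camera called the list higher without control 3 (adjusted p = 0.0355), after repeated quantile normalization (0.0404) and with the mean of a gene's probe sets (0.0158). Of 31 proteasome subunits none passed limma's test, also adjusted over the list alone, and the median was 0.046 (camera adjusted p = 0.519).

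Many muscle structure genes were lower after insulin. Of 61 tested sarcomere and contraction genes 31 fell, none rose and 30 did not pass, and 44 fell adjusted over the list alone. The median was -0.26 and camera called the list lower (adjusted p = 1.28e-18, and 0.0491 with an estimated correlation). Besides Myl2, Tcap (telethonin) fell by 0.70 ± 0.07 on the log2 scale (SE) and Kbtbd5 (Klhl40), which stabilizes thin filament proteins, by 0.58 ± 0.06. Myh7, the slow myosin heavy chain, fell by 0.69, and the creatine kinase gene Ckm by 0.30.

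The list of myogenic regulators and fusion genes was also called lower by camera (median -0.27, adjusted p = 2.04e-08, and 0.0491 with an estimated correlation). Of its 27 members 14 fell, 2 rose and 11 did not pass, and 20 fell and 2 rose adjusted over the list alone. The myogenic transcription factor gene Myod1 went from 12.07 ± 0.05 to 11.50 ± 0.09 (SD, n = 3), Myog fell by 0.27 and Mef2c by 0.39. The acetylcholine receptor genes Chrnd and Chrnb1 fell by 0.46 ± 0.07 and 0.39 ± 0.07 (SE). The rises were in Cdkn1c (0.31) and in Myf5 (0.29), a factor of undifferentiated myoblasts. With the brightest probe set alone, Myod1 (-0.31, limma adjusted p = 0.0748) and Chrnb1 (-0.23, 0.0835) did not pass.

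Markers of undifferentiated myoblasts and satellite cells went both ways. Of 16 members, Ccnd1, Cd34 (0.55), Met (0.51) and Myf5 rose, Id3 and Heyl (-0.44) fell and 10 did not pass, with 5 rises and 3 falls adjusted over the list alone. Their median was 0.0082 and camera did not call the list (adjusted p = 0.909).

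Several FoxO targets, which insulin represses through AKT, were lower. Of 30 FoxO targets and atrophy genes 15 fell, 1 rose and 14 did not pass (16 and 1 adjusted over the list alone), with a median of -0.25. Camera called the list lower (adjusted p = 3.62e-06, and 0.0491 with an estimated correlation). Fbxo32 (atrogin-1, a muscle ubiquitin ligase) went from 10.97 ± 0.09 to 9.97 ± 0.10 (SD, n = 3), Trim63 (MuRF1) fell by 0.69 and Pdk4, the kinase that restrains pyruvate dehydrogenase, by 0.65 ± 0.08 (SE). Ddit4 (REDD1), an inhibitor of mTORC1 that stress also induces, was the gene that rose, by 0.95 ± 0.11.

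Several genes of the insulin pathway itself were lower. In the insulin signalling list 10 of 46 members fell, 2 rose and 34 did not pass, with 15 falls and 4 rises adjusted over the list alone. Camera called it lower (median -0.15, adjusted p = 0.00414), which was lost with a correlation estimated from the arrays (adjusted p = 0.103 with an estimated correlation). Igf1r, the IGF-1 receptor, fell by 0.75 ± 0.09 on the log2 scale (SE), and Irs2, an insulin receptor substrate measured by 1 probe set, by 0.53 ± 0.10. Trib3 rose most in this list, and Gsk3a rose by 0.24. Insr, the insulin receptor, changed by -0.35 ± 0.14 and did not pass (limma adjusted p = 0.129). It did pass without control 2 (adjusted p = 0.0343), with the mean of its probe sets (0.0041), its brighter probe sets (0.0226) or its brightest one (0.0166).

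Irs1, the other main insulin receptor substrate gene, fell by 0.34 ± 0.09 (SE), a call close to the threshold (limma adjusted p = 0.0318). It was lost without control 2 (0.0719), insulin 1 (0.0971), insulin 2 (0.108) or insulin 3 (0.0815), and with no filter on dim genes (0.0583). Slc2a4, the insulin-responsive glucose transporter GLUT4, changed by -0.19 ± 0.09 (adjusted p = 0.184), passed with array quality weights (-0.25, 0.0233), and lay at 0.035 with its brightest probe set.

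Growth factor and early response lists were not called by camera. Of 22 genes of the IGF system and growth factors 4 rose and 6 fell, also adjusted over the list alone, with Stc1 at 1.43 and Igfbp3 at 0.68 against Hgf at -0.53 and Igf2 at -0.50. Their median was -0.047, their mean 0.026 and camera's direction down (adjusted p = 0.773). Immediate early and ERK feedback genes counted 5 rises and 9 falls among 35 (5 and 13 adjusted over the list alone), with a median of -0.09. Fosl1 (0.79), Atf3 (0.75) and Myc rose, while Ctgf (Ccn2) fell by 1.02 and Egr2 by 0.82. Camera did not call that list (adjusted p = 0.0703), but did without control 3 (0.0454) or insulin 1 (0.0498), and fry passed it (adjusted p = 0.0395).

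Some lipid synthesis genes rose. In the lipogenesis and SREBP-1 list 9 of 22 genes rose and none fell by limma (11 and 0 adjusted over the list alone), with a median of 0.23 and camera adjusted p = 1.26e-04 (adjusted p = 0.104 with an estimated correlation). Srebf1, encoding the SREBP-1 transcription factor, rose by 0.40 ± 0.06 on the log2 scale (SE), though its brightest probe set lay at -0.027. Slc25a1, the mitochondrial citrate carrier, rose by 0.55 ± 0.07, the acetyl-CoA synthetase gene Acss2 by 0.51 ± 0.07 and the desaturase gene Fads1 by 0.54 ± 0.07. Acaca and Fasn, the carboxylase and synthase of fatty acid synthesis, rose by 0.85 and 0.46.

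Among 20 cholesterol synthesis and SREBP-2 genes 8 rose and none fell, with 10 rises and 1 fall adjusted over the list alone. Camera called the list higher (median 0.21, adjusted p = 8.85e-05), though not with the other correlation (adjusted p = 0.11 with an estimated correlation). Lss (lanosterol synthase) rose by 0.66 ± 0.07 (SE), and the mevalonate pathway kinase genes Pmvk and Mvk by 0.62 ± 0.08 and 0.55 ± 0.07. Mvk did not pass with its brightest probe set alone (0.28, limma adjusted p = 0.0781).

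Glycolytic genes went both ways. Of 23 tested members 10 rose, 2 fell and 11 did not pass, also adjusted over the list alone. Slc2a1, the glucose transporter GLUT1, rose from 11.84 ± 0.06 to 12.60 ± 0.06 (SD, n = 3), Pfkl, the liver-type phosphofructokinase, by 0.63 ± 0.06 (SE) and Pgam1 by 0.43 ± 0.06. The muscle isoforms Pfkm and Pgam2 were those that fell, by 0.35 and 0.27. Hk2, the muscle hexokinase, changed by 0.015 ± 0.098 and did not pass (limma adjusted p = 0.940). The list was called higher by camera (median 0.055, adjusted p = 0.0195), but not with the other correlation (adjusted p = 0.282 with an estimated correlation), on ranks (0.0602), with the 50th percentile filter (0.143), with brighter probe sets (0.0759) or with the brightest one (0.194), which also left Pgam1 at 0.26 (0.0604). Its median was 0.098, 0.11 and 0.033 without control 1, 2 or 3, 0.034, 0.090 and 0.092 without insulin 1, 2 or 3, 0.034 after centring and 0.10 with the mean of probe sets.

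Of 20 hypoxia response genes 7 rose and none fell by limma (10 and 0 adjusted over the list alone), and camera called the list higher (median 0.26, adjusted p = 1.11e-04, and 0.0491 with an estimated correlation). Ero1l (Ero1a), an oxidase of the endoplasmic reticulum, rose by 1.61 ± 0.13 (SE). Slc2a1, Ddit4 and Hmox1, which stand on other lists too, were among those that rose, and Ndrg1 rose by 0.46. Vegfa (0.18, limma adjusted p = 0.202) and Bnip3 (0.15, 0.383) were among the 13 that did not pass. Fatty acid oxidation genes counted 3 rises and 5 falls among 32, also adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.378). Cpt1a, which admits fatty acids to mitochondria, fell by 0.57 and Fabp3 by 0.44, while Acot2 rose by 0.51.

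The medians of the mitochondrial lists lay between -0.047 and 0.067. Of 25 fusion and fission genes 2 fell and 23 did not pass, also adjusted over the list alone. Pink1, the kinase that marks damaged mitochondria, fell by 0.68 ± 0.07 on the log2 scale (SE) and Smcr7 (Mief2), which recruits the fission protein DRP1, by 0.35 ± 0.07. Mfn2 (mitofusin 2) changed by -0.044 ± 0.082 (limma adjusted p = 0.768), and 1700020C11Rik (Mtfp1) by 0.24 ± 0.09 (adjusted p = 0.125), passing with array weights (0.0209), the mean of its probe sets (0.036) or its brightest probe set (0.0262). The list's median was 0.032, its mean -0.0089 and camera's direction down, without a call (adjusted p = 0.960). Biogenesis regulators had 2 falls among 24, also adjusted over the list alone, in Esrrg (-0.38) and Prkaa2 (-0.27), with a median of 0.036 (camera adjusted p = 0.960). Ppargc1a, the biogenesis coactivator PGC-1alpha, lay under the filter of 7.05 at 6.62 ± 0.17 in controls and 6.41 ± 0.24 after insulin (SD, n = 3), and was not tested.

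Of 78 nuclear-encoded oxidative phosphorylation genes 2 fell and 76 did not pass, with 1 fall adjusted over the list alone. The muscle isoforms Cox8b and Cox6a2 fell by 0.43 ± 0.06 and 0.37 ± 0.08 (SE), and Atp5j, a subunit of ATP synthase with 1 probe set, changed by -0.35 ± 0.11 without passing (limma adjusted p = 0.0786). Cox6a2 did not pass without control 2 (0.064), insulin 1 (0.0648) or insulin 2 (0.0622), and Atp5j did without control 1 (0.00942) and with array weights (0.00233). Atp5j also passed with the mean of probe sets (0.0439). With 1 probe set its values and its change of -0.35 were the same there, so only what the fit takes from other genes differed. Camera called the list lower (median -0.047, adjusted p = 0.0254), which was lost with the other correlation (adjusted p = 0.584 with an estimated correlation). The call was also lost without control 3 (0.181), after repeated quantile normalization (0.203), with array weights (0.0522) and with the brightest probe set (0.329).

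Mitochondrial ribosome genes counted 4 rises, no fall and 73 not passed among 77, with 3 rises adjusted over the list alone. Mrps18b rose by 0.45 ± 0.08 (SE), Mrpl47 by 0.43 ± 0.08 and Mrpl40 by 0.34 ± 0.07. Camera called the list higher (median 0.067, adjusted p = 0.00722), but not with the other correlation (adjusted p = 0.79 with an estimated correlation) nor without control 1 (median 0.042, adjusted p = 0.117), on which the list's mean lay at -0.12 from its mean over the 6 arrays. Mrpl47 did not pass limma's test without insulin 2 (adjusted p = 0.051). Mrpl40 did not without control 2 (0.0531), insulin 1 (0.0542), insulin 2 (0.067) or insulin 3 (0.0522), nor with its brightest probe set (0.626). None of 7 genes of the mitochondrial genome passed, also adjusted over the list alone (median -0.042, camera adjusted p = 0.773). Of 27 genes of the tricarboxylic acid cycle Idh3a rose (0.25) and Brp44 (Mpc2) fell (-0.41), neither of which passed adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.951).

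Candidate genes at type 2 diabetes loci were not called as a list. Of 43 tested genes 5 rose, 2 fell and 36 did not pass, also adjusted over the list alone. Ccnd2 (cyclin D2) rose by 0.86, Pparg by 0.65 ± 0.09 on the log2 scale (SE) and Prc1, also a cell cycle gene, by 0.55, as did Hmga2 (0.41) and Klhdc5 (Klhl42) (0.24). Tspan8 fell by 0.95, and Irs1 was the other fall. Their median was -0.012, their mean 0.019 and camera's direction up (adjusted p = 0.960).

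Fibroblast and matrix markers were lower in part. Of 22 members 6 fell, 1 rose and 15 did not pass, with 8 falls and 3 rises adjusted over the list alone. Tagln (transgelin) fell by 0.93 ± 0.08 on the log2 scale (SE) and Dcn (decorin) by 0.57 ± 0.07, while Tnc (tenascin C) rose by 0.69 ± 0.08. Camera called the list lower (median -0.16, adjusted p = 0.0235), not with the other correlation (adjusted p = 0.475 with an estimated correlation), without control 1 (median -0.086, adjusted p = 0.082), on ranks (0.0597) or with array weights (0.0776). Of 15 adipocyte markers Cebpa fell by 0.75 ± 0.06, Car3 by 0.61 ± 0.07 and Pnpla2 by 0.31, while Pparg rose and 11 did not pass. Adjusted over the list alone there were 4 falls and 1 rise. Car3 did not pass with its brightest probe set (-0.35, limma adjusted p = 0.0887).

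Camera called the adipocyte list lower (median -0.08, adjusted p = 0.0259), a call lost with the other correlation (adjusted p = 0.465 with an estimated correlation). It was also lost without control 1 (0.117) or insulin 3 (0.0952), with the 50th percentile filter (0.092), array weights (0.0522), brighter probe sets (0.0793), the brightest probe set (0.424) and the mean of probe sets (0.0638). The median was -0.13 without control 2, -0.15 without control 3, -0.13 without insulin 1, -0.17 with the 50th percentile filter and -0.20 with array weights. Endothelial and smooth muscle markers had 1 rise (Flt1, 0.49) and 1 fall (Cnn1, -0.38) among 13, also adjusted over the list alone, with a median of -0.053 (camera adjusted p = 0.420). None of 15 osteoblast and cartilage markers passed, also adjusted over the list alone, with a median of -0.011, a mean of 0.0054 and camera's direction down (adjusted p = 0.960). Macrophage and leukocyte markers had 3 members above the filter, with a median of 0.098, and erythroid and liver markers 2, with a median of -0.065. None of these passed, and both lists were too short to test.

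Of 39 autophagy and lysosome genes 4 fell, 2 rose and 33 did not pass, with 6 falls and 2 rises adjusted over the list alone. Map1lc3a, an LC3 gene, fell by 0.47 ± 0.07 on the log2 scale (SE) and Hexa, a lysosomal hexosaminidase subunit, by 0.36 ± 0.07, while Tcfe3 (Tfe3), a transcription factor of lysosomal genes, rose by 0.38 ± 0.07. Hexa did not pass without insulin 2 (limma adjusted p = 0.0552) or with its brightest probe set (0.0922). Camera called the list lower (median -0.066, adjusted p = 0.0189), which was lost with the other correlation (adjusted p = 0.112 with an estimated correlation), without control 3 (0.0626), without insulin 2 (0.0505) and with the brightest probe set (0.174), and the median was -0.10 without insulin 3. NF-kB and inflammation genes counted 2 rises, in Ptgs2 (0.95) and Cebpb (0.29), and 2 falls, in Cxcl12 (-0.31) and Cebpd (-0.29), among 24, with 4 rises and 2 falls adjusted over the list alone. Their median was -0.047 (camera adjusted p = 0.610). Ifih1 alone rose (0.33) among 20 interferon response genes, with no call adjusted over the list alone. That list had a median of -0.042, a mean of 0.0036 and camera's direction down (adjusted p = 0.909).

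**Figure D2:**
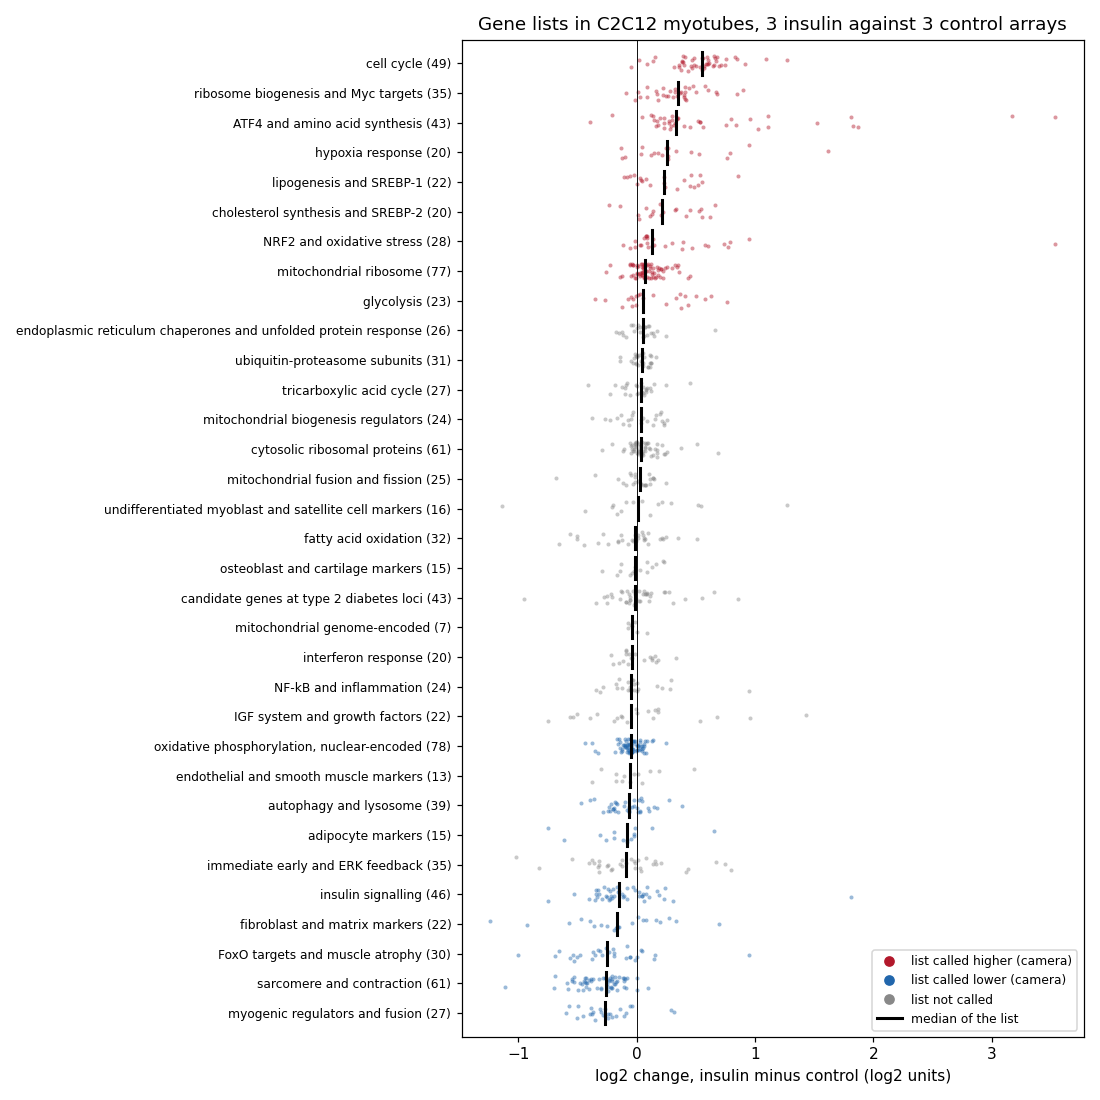
Log2 change, insulin minus control, of each tested member of the 33 gene lists (points), with the list median as a black bar and the number of members in brackets. Red lists were called higher and blue ones lower by camera with the preset correlation, and the medians run from -0.27 for myogenic regulators to 0.55 for the cell cycle.

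In total camera called 17 of 33 lists, 9 higher and 8 lower. With an estimated correlation 7 calls held, namely cell cycle, ATF4, sarcomere, ribosome biogenesis, myogenic regulators, FoxO targets and hypoxia. All of these except ATF4 share 1 tied Benjamini-Hochberg value just under the threshold, which the hypoxia list sets. Those calls thus hold or fail together and are not separate support. Fry also passed 17 lists, though not the same ones. Fry did not pass the mitochondrial ribosome (adjusted p = 0.178) or oxidative phosphorylation (0.0686), which camera called, and passed the endoplasmic reticulum chaperones (0.0373) and the immediate early genes (0.0395), which camera did not call.

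Single probe sets showed more rises than falls. Of 169103 tested probe sets 8235 passed limma's test with Benjamini-Hochberg adjustment, 5804 higher and 2431 lower, so 70.5% of the calls were rises. Among those with 1 gene symbol 5454 rose and 2296 fell, and among those with several symbols 136 rose and 16 fell. Probe sets with no symbol in the annotation counted 214 rises and 119 falls, led by probe set 10537178, which went from 6.48 ± 0.23 to 9.06 ± 0.04 (SD, n = 3). The number of called probe sets fell to 4124, 1309 and 5224 without control 1, 2 or 3, to 698, 553 and 429 without insulin 1, 2 or 3, and to 2960 with no filter. It rose to 14395 with an intensity trend and to 31205 with array quality weights, where 55.6% of the calls were rises.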

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

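The calls of at least 1.5-fold were chosen only after the result was seen. Genes past the threshold numbered 421 at that limit, 5007 with array quality weights and 3436 with the mean of a gene's probe sets, and from 1045 to 2449 over the 6 fits that leave out 1 array. The called probe sets numbered 2960 with no filter, 14395 with an intensity trend, 31205 with array quality weights and from 429 to 5224 with 1 array left out. Camera with an estimated correlation called 7 lists, all but ATF4 at the same tied value just under the threshold. Fewer arrays leave fewer degrees of freedom, and the cause of the other shifts was not tested.

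Same-numbered arrays deviated from their group means with correlations of 0.02, 0.19 and 0.00, so the numbers are not known to pair the cultures, and not every array correlated best with its own number. With the replicate number as a block, 1970 genes, 656 probe sets and 17 lists were called. Among the named genes Irs1 then missed the threshold (limma adjusted p = 0.0531) and Atp5j passed it (0.0422), and no other named gene or list changed its call.

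Directions turned where nothing was called, except for Avil and Srebf1. With the brightest probe set, Avil lay at -0.17, Srebf1 at -0.027, Hk2 at -0.041, Slc2a4 at 0.035, undifferentiated markers at -0.078, the tricarboxylic acid cycle at -0.00064 and the proteasome at -0.0052. Quantile normalization put Hk2 at -0.0055 and undifferentiated markers at -0.0045, and centring put them at -0.0058 and -0.012. Array quality weights gave Hk2 -0.011, Mfn2 0.026, the IGF list 0.018, fatty acid oxidation 0.0028 and undifferentiated markers -0.090. The 50th percentile filter gave diabetes loci 0.018, fatty acid oxidation 0.00087 and osteoblast markers 0.061. Brighter probe sets gave diabetes loci 0.015, endothelial markers 0.084 and undifferentiated markers -0.092. With 1 array left out, values ran from -0.084 to 0.098 for Hk2, -0.085 to 0.036 for Mfn2, -0.041 to 0.036 for diabetes loci, -0.041 to 0.0069 for fatty acid oxidation, -0.049 to 0.019 for interferon, -0.011 to 0.062 for biogenesis regulators, -0.068 to 0.0049 for the mitochondrial genome, -0.065 to 0.041 for osteoblast markers and -0.044 to 0.058 for undifferentiated markers. The cause of these turns was not tested. With the brightest probe set, Slc7a11, Chrnd, Dkc1, Lss, Map1lc3a, Mrpl47, Pfkl, Postn, Slc25a1 and Tnc changed less by over 1.5 times and still passed, as Kbtbd5 (Klhl40) did with the mean of probe sets.

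Of 428 list values under other settings 387 kept direction and side of the threshold, as did 175 of 198 with 1 array left out. For the 77 named genes it was 730 of 761 and 444 of 462. No signal over background was used here, so the dimmest genes could not be told from background.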

Other observations

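Chosen only after the result was seen were all gene families and lists below, and the tests of genes matched on level, of undifferentiated cells, of endoplasmic reticulum chaperones and of TGF-beta and BMP targets. Cytosolic tRNA synthetases, which charge tRNAs with amino acids, rose in part. Of 19 genes 8 rose, none fell and 11 did not pass (15 and 0 adjusted over the list alone), with a median of 0.25, and Yars rose by 0.43, Aars by 0.34 and Lars by 0.34. Camera called the family higher over the 11 families tried (adjusted p = 3.37e-06), not with the other correlation (adjusted p = 0.132 with an estimated correlation), and 9 of the 19 genes stand on the ATF4 list. Mitochondrial tRNA synthetases had a median of 0.037 with an SD of 0.14 and 2 rises among 16 (Sars2 and Wars2, both 0.34), which argues against a like rise of all tRNA synthetases. Among 29 amino acid transporters 10 rose and 3 fell. Besides Slc7a11, the glutamine carrier gene Slc1a5 rose by 1.03, Slc1a4 by 0.84 and Slc7a3 by 0.76, while Slc43a2 fell by 0.78, Slc43a1 by 0.55 and Slc1a3 by 0.58 (camera adjusted p = 0.107).

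Small nucleolar RNA genes, which guide the modification of ribosomal RNA, counted 5 rises and no fall among 21, led by Snord16a at 0.70 (median 0.20, camera adjusted p = 0.00112, and adjusted p = 0.132 with an estimated correlation). RNA polymerase subunits counted 3 rises among 26, in Polr3g (0.65), Polr1e (0.45) and Polr1b (0.34), with camera adjusted p = 0.0283 and adjusted p = 0.374 with an estimated correlation. Histone genes had 8 rises and 3 falls among 39 (camera adjusted p = 0.0531), with Hist1h1a (H1f1) at 0.88 and Hist2h3c1 (H3c14) at -0.58. Translation initiation factors had 1 rise among 55 (Eif1ad, 0.39, camera adjusted p = 0.0604), and glutathione S-transferases 2 among 15 (Gsta3 and Gsta4, camera adjusted p = 0.187). Of 40 collagens Col12a1 fell by 1.00 and Col18a1 rose by 0.44 (camera adjusted p = 0.219). Zinc finger genes named Zfp counted 7 rises and 7 falls among 259 (camera adjusted p = 0.291). None of 58 olfactory receptor genes passed limma's adjusted threshold, also adjusted over the list alone (median -0.039, camera adjusted p = 0.106). No family's median changed sign under either scaling.

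The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2274 genes and the highest other split 0, and for probe sets it gave 8235 against 4; in each of these counts, and for lists, 1 split, the real one, reached the real value. For lists the real split gave 17 and the others 4 to 14 with the preset correlation, so lists were called in every split. With an estimated correlation the real split gave 7 against 0 and with fry 17 against 0. Every other split mixes the groups, so their difference enters its spread and low counts of genes are set in advance.

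Most cell cycle genes rose while 31 of 61 sarcomere genes fell. Scaling of the arrays, alike for all genes or by their level, is argued against, as cell cycle genes exceeded sarcomere genes of the same level (within 0.25) by a median of 0.679 (SD 0.339, 46 pairs with 24 cell cycle genes). So is a lone array, as the list medians were at least 0.507 and at most -0.260 in every fit that left 1 array out. Whether the insulin cultures held a larger share of undifferentiated cells stays open. Outside the cell cycle list, 15 markers of such cells had a median of -0.032 (SD 0.41) against 0.55 for the cell cycle. They did not rise together, but 3 rose (Cd34, Met and Myf5) and 2 fell. Markers that go both ways cannot tell whether that share changed. An effect of insulin, the treatment compared here, on proliferation or on differentiation was not tested and stays open, and may act in the myotubes or in cells that did not fuse, which these arrays do not separate.

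More probe sets rose than fell. The share of rises among called probe sets was 70.5%, and 65.8% among the brighter probe sets, which argues against dim probe sets as the whole source. Scaling stays open, since RMA had already equalized the arrays (medians of 8.79 to 8.82) and the 65.3% left after centring excludes nothing. At the level of genes the excess was smaller, with 60.1% of calls rising, 54.1% after centring and 52.1% with array quality weights, which also brought the share among probe sets to 55.6%. A biological cause was not tested.

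Camera called the ATF4 list higher and did not call the endoplasmic reticulum chaperones, which fry passed as moving up on balance (adjusted p = 0.0373). The chaperone median of 0.052 (SD 0.16) lay below the ATF4 median of 0.34 by more than that SD. The chaperones thus did not rise as far as the ATF4 genes. As chaperones cover only part of an unfolded protein response, such a response of that compartment stays open as a source. Whether a mitochondrial stress response contributes stays open too. Of 18 mitochondrial chaperones and proteases, 3 of them also on fixed lists, Lonp1 (0.72), Hspd1 (0.56), Hspa9 (0.32) and Timm44 (0.26) rose and none fell. Adjusted over the list alone there were 6 rises and 1 fall, of Clpx (-0.25). The median of these 18 genes was 0.11 (SD 0.24, 0.088 after centring), which also lay below the ATF4 median. Camera called them higher over the 3 lists tried (adjusted p = 0.0399), a weak shift that was lost with the other correlation (adjusted p = 0.310 with an estimated correlation). Amino acid use by growing cells, as a direct effect of insulin, stays open and was not tested.

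The 15 other neuronal genes tried did not rise together with Nefm. Their median was 0.0097 (limma's camera adjusted p = 0.610) and turned to -0.017 after quantile normalization and -0.011 after centring. Of these genes Tubb3 (0.53) and Mtap2 (Map2) (0.33) rose, Mapt (-0.44) and Ncam1 (-0.26) fell and the others did not pass. Whether lower TGF-beta or BMP signalling goes with the falls of Mfap5, Postn and Id3 stays open. The 22 targets tried outside the named genes, 7 of them on fixed lists, had a median of -0.11 (camera adjusted p = 0.0399 over 3 lists). That call was lost with the other correlation (adjusted p = 0.310 with an estimated correlation). Among these targets Itgb5 (-0.71), Cnn1 (-0.38) and Junb (-0.33) fell, Timp3 (0.27) rose and the others did not pass. Those not passing went both ways, with Id1 at -0.17 and Smad6 at -0.14 against Smad7 at 0.19 and Id2 at 0.11.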
